A study of Mus musculus with 8 samples.

How the data were processed

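Whole cells of pooled mouse embryos were profiled by droplet single-cell RNA sequencing with 3' end capture. Per the labels' protocols, the head and the first 7 somite pairs were removed, the remaining body of 15 embryos from 3 litters was pooled per sample, dissociated enzymatically and strained, and 1 control and 1 high-fat sample were collected per day on 2 days. The labels do not say that the replicate number marks the day. Samples of E9.5 that the series describes are not analysed here. The authors deposited, for each sample, a filtered matrix of raw UMI counts per gene and cell barcode with its gene and barcode lists, and per the file headers these counts were made with Cell Ranger 7.0.1. The submitters' processing notes name the build mm10, Cell Ranger and Seurat 5, without saying what was done with Seurat. The deposited counts were whole numbers, and the smallest total of a barcode was 500 or 501, depending on the library. How reads of near-identical genes were shared out is not given in the sources used here.

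The matrices of both control samples of E13.5 were identical, as were those of both high-fat samples of E13.5, and each pair was counted once. Other pairs of libraries shared between 9 and 26 barcodes. This left 2 distinct libraries per diet at E11.5 and 1 per diet at E13.5. The libraries held 7645 and 7314 (control, E11.5), 6549 and 6675 (high-fat, E11.5), 10247 (control, E13.5) and 8597 (high-fat, E13.5) barcodes. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, 7357, 7049, 6291, 6441, 9600 and 7665 in the same order. Median mitochondrial shares lay between 2.60 and 2.85%. Doublets were scored with the scrublet method of scanpy 1.11.5. Its automatic threshold marked between 0 and 3.13% of cells and was judged not to have worked, so the highest scores up to the rate of 0.8% per 1000 barcodes were removed, 475, 440, 361, 374, 798 and 572 cells.

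Cells of all libraries were clustered together without batch correction on 2500 variable genes, 40 principal components and 20 neighbours per cell, with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 on a graph of shared neighbours pruned below 1/15, in 5 iterations with seed 1. This gave 44 clusters. A cluster took the name of a cell type when at least 3 of that type's markers were raised by more than 0.5 on the log2 scale (prior of 10 CPM) and seen in at least 10% of its cells, when it had at least 50 cells and at most 50% doublets; a cluster whose 10 leading genes held more markers of another class than of its own stayed unnamed (clusters 4, 16, 23 and 32), and the marker lists of 28 cell types were fixed, but these limits were set after the data were seen. Clusters 4 and 32 carried mesenchymal markers but stayed unnamed. They held 11.0 and 10.7% of control cells and 11.8 and 8.84% of high-fat cells at E11.5, and 0.386 and 0.733% at E13.5. Mesenchyme, limb mesenchyme and sclerotome clusters formed the mesenchymal-like class. As types were rebuilt from clusters, all classes are called "like".

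Counts were summed per library and class and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM scaling and its filter on low counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. Diet was tested at E11.5 with 2 libraries per diet. Stage was tested with diet as a term, in 4 libraries of E11.5 against 2 of E13.5. Other classes were tested where each library had at least 50 cells. Shares were tested with edgeR on cell numbers per class with the total of used cells as library size, over classes of at least 20 cells. Gene lists, 33 in number, were tested where at least 5 members were measured with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. The lists, markers, tests and the rule for named genes were fixed before the data were examined. Ero1a and Hbb-bh0 of the lists were not matched to a gene of the files. The rule takes the 10 highest and 10 lowest fold changes among genes past the threshold with a mean log2 CPM of at least 4 and every high-fat library on one side of every control library, and up to 4 members past the threshold per list. Gene models without a name, and mitochondrial and ribosomal protein genes, were counted and named only as members of a list. Differences between diets are high-fat minus control. Values are means ± SD of CPM, and errors of log2 differences are standard errors.

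At E13.5, where 1 library per diet has no replicate check, log2 ratios of CPM are given for genes with at least 200 UMIs in both libraries together, with exact 95% intervals. Intervals of ratios and shares cover counting error only. A list's median was placed among 10000 random lists of the same size matched on mean expression. A term for the interaction of diet and stage could not be fitted.

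Exon and intron lengths and coordinates came from GENCODE vM21 (GRCm38), in which 32235 of 32285 gene identifiers were found. After the trend with gene length had been seen, an offset per library was added as an alternative. It was a smooth trend (mgcv 1.9.3, basis size 6) over log2 exon length and log2 intron length plus 100 bases, fitted on genes with a mean log2 CPM above 3. Further alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, leaving out each library, the replicate number as a block, at least 1500 genes and at most 5% mitochondrial UMIs per cell, doublets kept, 1 fit of all libraries, Leiden resolution 2 (68 clusters), cells thinned to at most 5000 UMIs, shares without erythroid cells, camera with an estimated correlation, fry, and control libraries alone for stage. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used for the other steps.

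The steps were tested on simulated counts with known fold changes. With 100 genes changed 1.5-fold and 100 changed 2-fold, the test of the mesenchymal-like class found 100 and 100 with 18 false calls among 17158 genes. For the myogenic-like class it found 64 and 99 with 14 false calls among 13508, and for all cells 99 and 100 with 45 among 20860. For stage it found 99 and 100 with 23 among 18377 genes in the mesenchymal-like class, and 85 and 100 with 22 among 14283 in the myogenic-like class. When a length trend was added to the simulated counts, 3929 and 818 false calls arose in the mesenchymal-like and myogenic-like class without the offset and 21 and 17 with it. The added trend was linear in log2 exon length and equal in both high-fat libraries. As the offset fits a trend over the same length, its removal was fixed in advance. This does not show that the offset is right for the measured trend, which also differed between replicates of 1 diet. For the list test the matrix list was raised 1.5-fold and each gene was drawn independently. Camera with the preset correlation found the raised list and no other, and with the estimated correlation it missed it (camera adjusted p = 0.066 and 0.13). As simulated genes were not correlated, this does not show which setting is right for list members that move together. The share test found a class changed 2-fold in 88 of 100 draws, with 17 false calls in 1200.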

Results

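Single-cell transcriptomes were measured in mouse embryos of C57BL/6 dams fed either control or high-fat chow from 10 weeks ahead of mating. By its title, the series is about an origin in the embryo of fibrosis seen in offspring of obese mothers. The body from the 8th somite pair to the tail was dissociated, and every sample was a pool of 15 embryos from 3 litters. Per the labels these pools are separate samples, so that p-values measure the spread between pools and not between embryos. Of the 8 samples, 2 per diet came from embryonic day 11.5 (E11.5) and 2 per diet from E13.5. At E13.5 both matrices of a diet were identical and were counted as 1 sample, which left 6 distinct libraries. The total of unique molecular identifiers (UMIs) was 186923880 and 178032080 in the control and 251417905 and 156898302 in the high-fat libraries of E11.5. At E13.5 it was 256622421 for control and 244927192 for high-fat. After filtering, 6882 and 6609 control cells and 5930 and 6067 high-fat cells of E11.5 were used, with 8802 and 7093 cells at E13.5. The median used cell held 19891 and 19734 UMIs in the control and 31404.5 and 18109 UMIs in the high-fat libraries of E11.5.

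At E11.5 the high-fat libraries held fewer neural progenitor-like cells and more chondrogenic-like and erythroid-like cells. Neural progenitor-like cells, whose larger cluster was led by Fabp7, Sox2 and Hes5, made up 12.8% ± 1.72 of control and 7.41% ± 0.753 of high-fat cells (SD, n = 2 libraries per diet), a log2 difference of -0.79 ± 0.152 (SE; edgeR adjusted p = 2.8e-04). Chondrogenic-like cells, at this stage mostly cluster 10, led by the limb and joint genes Tbx15, Shox2 and Osr2, made up 4.71% ± 0.243 and 7.61% ± 0.488 (log2 0.69, edgeR adjusted p = 0.0011), and erythroid-like cells 6.71% ± 0.485 and 9.69% ± 2.37 (log2 0.53, edgeR adjusted p = 0.0081). Endothelium-like, neuronal-like and epithelial-like cells were lower in the high-fat libraries, with log2 differences of -0.68, -0.45 and -0.43 (edgeR adjusted p = 0.022, 0.022 and 0.035). Mesenchymal-like cells, the class that produces most interstitial matrix, made up 30.2% ± 0.426 and 32.7% ± 1.15, and myogenic-like cells 3.87% and 4.98%. Neither of these passed the test (edgeR adjusted p = 0.55 and 0.063). In all, 6 of 13 classes passed, 2 higher and 4 lower, and 8 did at an unadjusted p under 0.05. The test shares its estimate of spread across the 13 classes, so its p-values do not measure the spread of a class alone. SEs were 0.157 for chondrogenic-like and 0.153 for erythroid-like cells, whose high-fat SDs were 0.488 and 2.37. Shares of 1 total are not independent, and an exact permutation test of 2 against 2 libraries could not reach 0.05. With the stricter cell filter 3 classes passed, and erythroid-like (edgeR adjusted p = 0.25), epithelial-like (0.092) and neuronal-like cells (0.18) did not. Without control replicate 1 none of these calls was left (3 at an unadjusted p under 0.05), without control replicate 2 only that of neural progenitor-like cells was (edgeR, 4 at an unadjusted p under 0.05), and without high-fat replicate 2 the calls of endothelium-like (adjusted p = 0.079) and epithelial-like cells (0.23) ended. Without high-fat replicate 1 those of erythroid-like (adjusted p = 0.23) and neuronal-like cells (0.30) ended, while myogenic-like (log2 0.51, 0.028) and neural crest-like cells (log2 0.59, 0.037) passed, and dissociation, straining and the pooling of embryos can set shares.

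**Figure D1:**
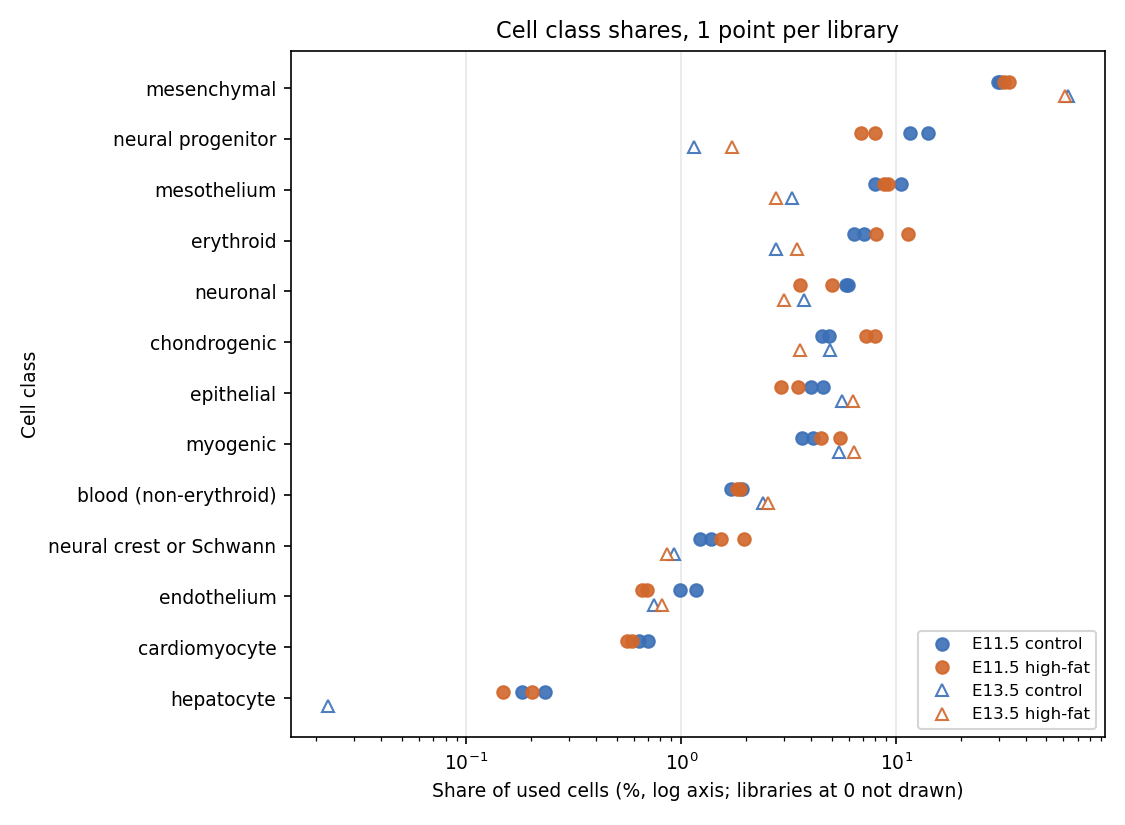
Share of used cells per class (%, log axis), 1 point per library, circles for E11.5 and triangles for E13.5, blue for control and orange for high-fat; libraries at 0 are not drawn. Both high-fat circles of the neural progenitor class (6.88 and 7.94%) lie below both control circles (14.0 and 11.6%).

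Within the mesenchymal-like class at E11.5, Hoxd13 and the long genes Dlg2, Pcdh15, Trpm3 and Plxna4 were higher in embryos of high-fat dams, and Camk1d, Lars2 and Gadd45b were lower. Globin genes, markers of erythroid cells, rose more than Hoxd13, with Hbb-bt at 1.35 and Hbb-y at 1.22, and are treated further on. Hoxd13 (ENSMUSG00000001819, chromosome 2, 74668310 to 74671599, GRCm38), a patterning gene of the digits and the body end, rose from 17.9 ± 1.93 to 34.2 ± 0.12 CPM (UMI counts scaled to a common library total; SD, n = 2 per diet), a log2 difference of 0.84 ± 0.071 (SE; edgeR adjusted p = 0.0017). Dlg2 (ENSMUSG00000052572, chromosome 7, 90476672 to 92449247), a synaptic scaffold gene of great length, rose by 0.82 ± 0.063 (edgeR adjusted p = 0.000945), and Pcdh15, Trpm3 and Plxna4, which are also long, rose by 0.81, 0.81 and 0.78. The calcium-dependent kinase gene Camk1d (ENSMUSG00000039145, chromosome 2, 5293457 to 5714515) fell by 1.06 ± 0.104 (edgeR adjusted p = 0.00187), and the mitochondrial leucyl-tRNA synthetase gene Lars2 (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666) fell by 0.94 ± 0.064 (edgeR adjusted p = 0.000605). Set against all other cells of the same libraries, Camk1d and Lars2 were at -0.0732 and 0.00305. At Leiden resolution 2 both were among the 10 leading genes of cluster 26, which had a median of 1092 UMIs. Gm42418, which overlaps ribosomal RNA sequence, was another of those leading genes. The growth arrest gene Gadd45b fell by 0.86, Vtn, which codes for the adhesion protein vitronectin, by 0.86, muscle enolase Eno3 by 0.73, and the linker histone genes Hist1h1e and Hist1h1b by 0.70 and 0.63. In all 4828 of 17395 genes passed, 2210 higher and 2618 lower, and 6838 did at an unadjusted p under 0.05. Without control replicate 1 the count was 957 and without control replicate 2 it was 2934, each with a lone control library assumed to vary like the high-fat ones; it was 2826 with cells thinned to 5000 UMIs. The difference was not shown to belong to this class: set against that of all other cells of the same libraries, no gene passed in edgeR (1736 did at an unadjusted p under 0.05).

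Between the diets, fold changes at E11.5 rose with gene length in every class with at least 50 cells in each library. In the mesenchymal-like class the rank correlation with exon length was 0.588 across 7260 genes, which are not independent replicates, and in the other classes it lay between 0.405 (non-erythroid blood) and 0.579 (myogenic-like). Between replicates of 1 diet in the mesenchymal-like class it was 0.327 for control and -0.363 for high-fat, and between the 2 libraries of E13.5 it was 0.206. With a per-library offset for exon and intron length, added after the data were seen, the correlation was 0.0653 and 2637 genes passed, of which 1984 were among the 4828. Of those 2637 genes 53.6% were higher, against 45.8% without the offset. With the offset the long genes Dlg2 and Pcdh15 were at 0.33 each and still passed. Counts with it are given for some of the lists.

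**Figure D2:**
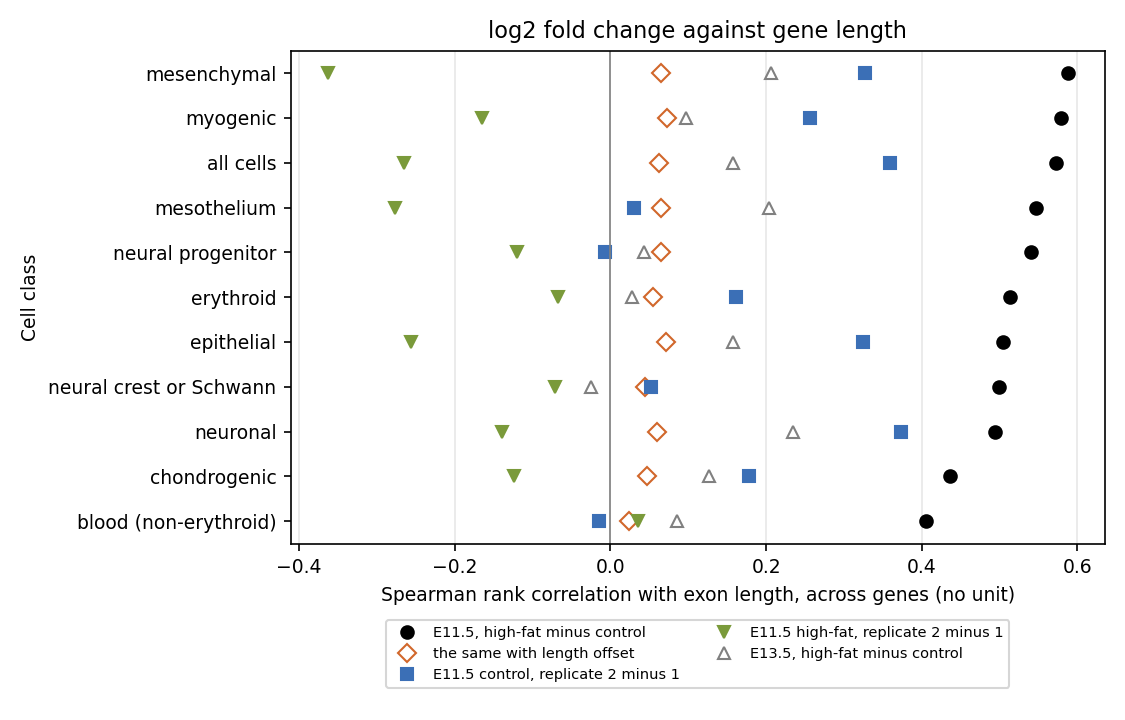
Rank correlation of log2 fold changes with exon length across genes (x axis, no unit) for each class; filled circles are high-fat minus control at E11.5, open diamonds the same with the offset, squares and filled triangles the difference between replicates of the control and of the high-fat diet, and open triangles the diets at E13.5. The filled circles lie between 0.405 and 0.588, to the right of every other symbol of their class.

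Genes of the extracellular matrix changed in both directions in the mesenchymal-like class. Of 53 members 9 rose and 7 fell, with the same numbers adjusted over the list alone and 3 in each direction with the length offset. Members that fell include Pcolce (-0.52 ± 0.055), which aids the processing of procollagen, and Mfap2 (-0.44 ± 0.058), a component of microfibrils, at edgeR adjusted p of 0.00197 and 0.00226. The small proteoglycan gene Lum (-0.40, edgeR adjusted p = 0.00694) passed as well, but not with the offset (-0.18, 0.22). As a list the extracellular matrix did not stand apart (camera adjusted p = 0.58). Nor did TGF-beta signalling (camera adjusted p = 0.52), the myofibroblast list (0.57), or the fibro-adipogenic and adipogenic lists (0.97 for both). Over all tested genes of the class 27.8% were called, the share to set beside the counts given here. Of 25 members of TGF-beta signalling 5 rose and 3 fell, likewise adjusted over the list alone, and 7 rose and 1 fell with the offset. Ltbp1, which stores latent TGF-beta in the matrix, rose from 77.9 ± 6.72 to 122 ± 5.48 CPM (log2 0.56, edgeR adjusted p = 0.002). The repressor gene Ski rose by 0.42 and the ligand gene Tgfb2 by 0.33. Among 14 myofibroblast and contractile genes 2 rose and 4 fell (3 and 5 adjusted over the list alone; 1 and 2 with the offset), with tropomyosin Tpm2 at -0.42. Of 19 markers of fibro-adipogenic progenitors 2 rose and 4 fell, with the same numbers adjusted over the list alone. Tcf7l2, a Wnt effector and marker of connective tissue fibroblasts, rose by 0.52 ± 0.051, and the growth factor receptor gene Pdgfrb fell by 0.53 ± 0.051 (edgeR adjusted p = 0.00187 for both). Of 18 adipogenic genes 6 rose and 5 fell, again also adjusted over the list alone, and 2 rose and 3 fell with the offset, among them Prdm16, a regulator of brown adipose fate, at 0.65 ± 0.051, and Plin2, a coat protein of lipid droplets, at -0.39.

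Without the length offset most of the called genes of oxidative phosphorylation, fatty acid oxidation, glycolysis and the cell cycle fell. Of 48 genes of oxidative phosphorylation 2 rose and 29 fell, also adjusted over the list alone, with a median of -0.202 (camera adjusted p = 8.3e-05, and adjusted p = 0.76 with an estimated correlation). The complex I gene Ndufb10 went from 226 to 185 CPM (-0.38 ± 0.062, edgeR adjusted p = 0.00326), and the ATP synthase gene Atp5k rose by 0.52. With the length offset 8 of the 48 rose and 6 fell, and Ndufb10 was at -0.13 (edgeR adjusted p = 0.071). Of 27 genes of fatty acid oxidation and PPAR targets 13 fell (14 fell and 1 rose adjusted over the list alone), and 6 fell with the offset (camera adjusted p = 0.012, and adjusted p = 0.76 with an estimated correlation). Angptl4, a PPAR target, and Eci1, an isomerase of unsaturated fatty acids, fell by 0.57 and 0.44. In hypoxia and glycolysis 12 of 28 genes fell and 1 rose (15 and 3 adjusted over the list alone; 8 and 3 with the offset; camera adjusted p = 0.018, and adjusted p = 0.76 with an estimated correlation), while the hexokinase gene Hk2 rose by 0.55 ± 0.079 (edgeR adjusted p = 0.00264). Among 44 cell cycle genes 15 fell and 2 rose (17 and 2 adjusted over the list alone; 5 and 3 with the offset; camera adjusted p = 0.012, and adjusted p = 0.88 with an estimated correlation), among them the replication genes Gins2 (-0.44) and Tyms (-0.40). In the oxidative stress response 10 of 22 fell and 1 rose (11 and 1 adjusted over the list alone; 5 and 1 with the offset; camera adjusted p = 0.018, and adjusted p = 0.76 with an estimated correlation), with the peroxiredoxin gene Prdx6 at -0.42. The cell cycle was not called without control replicate 1 or high-fat replicate 2, when 8 and 6 lists were, and the oxidative stress response not without control replicate 1 or high-fat replicate 1. With the length trends removed 2 lists passed, fatty acid oxidation (camera adjusted p = 0.0216) and posterior Hox (8.19e-05), and fry called none of the 29 lists (10 at an unadjusted p under 0.05).

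Some Hox and hedgehog genes passed as well. Of 15 posterior Hox genes 6 rose, the same number adjusted over the list alone, and 8 rose with the offset. Hoxa13 and Hoxd12 were at 0.88 ± 0.110 and 0.52 ± 0.073 (edgeR adjusted p = 0.00215 and 0.00259). Of 15 anterior Hox genes 5 fell (6 adjusted over the list alone; 2 with the offset), with Hoxb2 at -0.49 ± 0.057 (edgeR adjusted p = 0.00201). The anterior list was lower as a group (camera adjusted p = 0.012, and adjusted p = 0.76 with an estimated correlation). The posterior list did not pass (camera adjusted p = 0.0503, and adjusted p = 0.76 with an estimated correlation). Of 14 genes of hedgehog signalling 5 rose, as they did adjusted over the list alone, and 3 rose with the offset. They include the receptor gene Ptch1 (0.34 ± 0.047) and the co-receptor gene Boc (0.52 ± 0.064), at edgeR adjusted p of 0.00257 and 0.00211. Of 26 genes of Wnt signalling 4 rose and 4 fell (5 and 5 adjusted over the list alone), with the ligand gene Wnt5a at 0.43. Of 30 myogenic genes 4 rose and 2 fell, and of 21 chondrogenic and osteogenic genes 5 rose and 3 fell, both unchanged when adjusted over the list alone. None of these 4 lists passed (camera adjusted p = 0.075 for hedgehog, 0.78 for Wnt, 0.57 for myogenic and 0.40 for chondrogenic and osteogenic genes). Over all tested genes of the class 27.8% were called. Limb clusters held 19.8 and 19.6% of the mesenchymal-like cells in the control and 26.9 and 27.4% in the high-fat libraries. Hoxd13 and Hoxa13 were at 0.59 and 0.58 within those clusters.

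The remaining lists give the setting of these changes. Over all tested genes of the class 27.8% were called, and none of the remaining lists that camera tested passed. Of 29 genes of cholesterol and fatty acid synthesis 6 rose and 8 fell (7 and 8 adjusted over the list alone). Of 22 inflammation and interferon genes 2 rose and 5 fell (2 and 6 adjusted over the list alone), with the interferon regulator gene Irf1 at -0.76 ± 0.068. Of 29 growth factor axis and imprinted genes 6 rose and 7 fell (7 and 7 adjusted over the list alone), and of 23 cell cycle inhibitors and p53 targets 3 rose and 6 fell (3 and 7 adjusted over the list alone). Of 32 immediate early and heat shock genes 6 rose and 12 fell (7 and 13 adjusted over the list alone), with the growth response genes Egr1 and Fosb at 0.56 and 0.58, and of 29 genes of the unfolded protein and integrated stress response 2 rose and 11 fell (2 and 15 adjusted over the list alone; 4 and 5 with the offset). Of 10 genes of the Lin28 axis 1 rose and 2 fell, also adjusted over the list alone, Lin28a itself at -1.28 ± 0.231 (edgeR adjusted p = 0.00467, and 0.062 without control replicate 1). Markers of other cell types moved too. All 3 embryonic globins tested and all 4 adult globins rose, also adjusted over the list alone, with Hbb-y (ENSMUSG00000052187, chromosome 7, 103851749 to 103853216) going from 64.6 ± 24.5 to 160 ± 9.48 CPM (log2 1.22 ± 0.183, edgeR adjusted p = 0.00282); near-identical globin copies can share reads. Hbb-y was at 2.01 in this class at Leiden resolution 2 and at 0.09 over all cells (edgeR adjusted p = 0.851). Free RNA in the droplets was not estimated, and erythroid-like cells made up 6.71% of control and 9.69% of high-fat cells. Of 9 hepatocyte markers 4 rose (5 adjusted over the list alone), of 11 neuronal markers 1 rose and 1 fell, and of 9 endothelial markers 1 fell, the last 2 unchanged when adjusted over the list alone. Of 13 mitochondrially encoded genes 5 rose and 1 fell (5 and 2 adjusted over the list alone), mt-Nd3 by 0.82 ± 0.072. Of 6 nuclear and ribosomal RNA background genes 1 rose and 2 fell, also adjusted over the list alone: Gm42418, which overlaps ribosomal RNA sequence, went from 2734 ± 178 to 1228 ± 130 CPM (log2 -1.25, edgeR adjusted p = 0.000605). The X inactivation, Y-linked and macrophage lists had no member past the threshold in edgeR, over all genes or adjusted over the list alone, with medians of 0.43, 0.18 and -0.21.

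**Figure D3:**
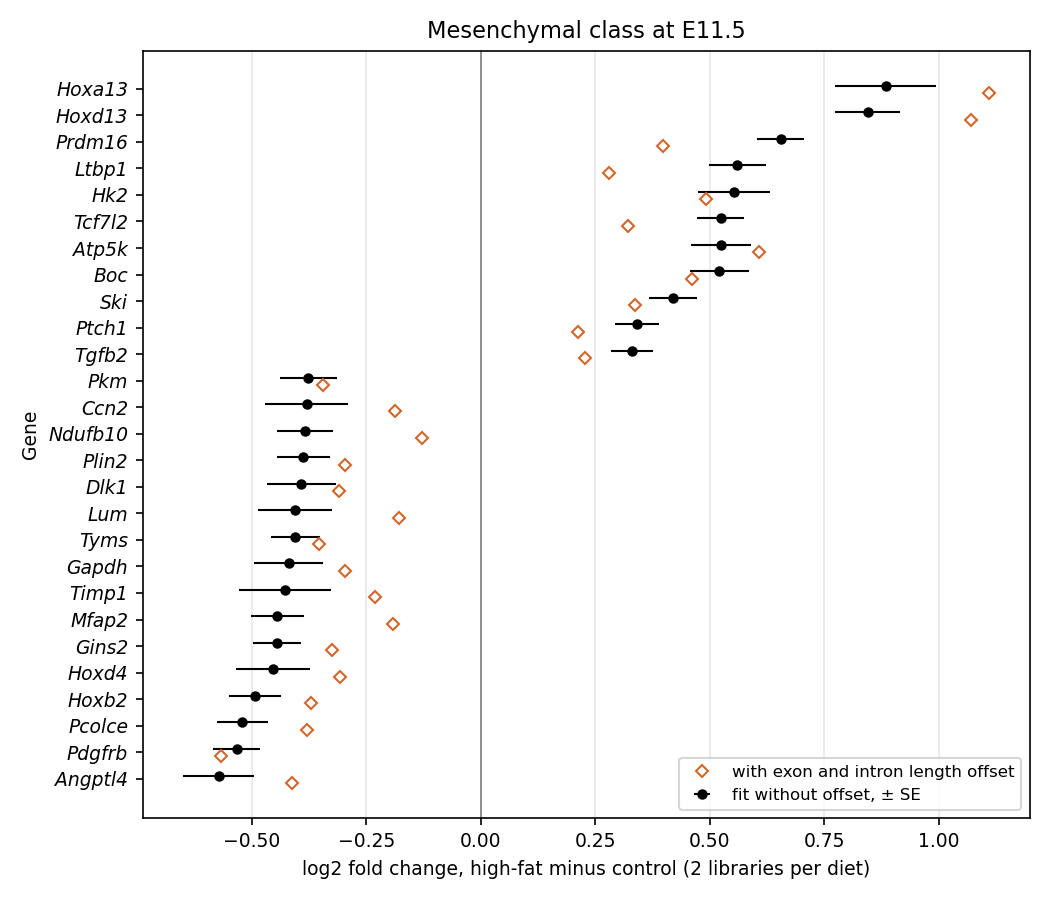
log2 fold change of named genes in the mesenchymal-like class at E11.5, high-fat minus control (x axis; error bars are ± SE, n = 2 libraries per diet), with the value under the length offset beside it. Hoxd13 lies at 0.84 and Pdgfrb at -0.53.

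In the myogenic-like class at E11.5 the immediate early genes Egr1 and Fosb and the metallothionein gene Mt1 were higher in the high-fat libraries, and the paraxial mesoderm regulator Tcf15 and the muscle determination gene Myod1 were lower. Egr1 went from 405 to 737 CPM (0.76 ± 0.063, edgeR adjusted p = 0.0202) and Mt1 from 6.34 to 23.8 CPM (1.81 ± 0.16, edgeR adjusted p = 0.0202). Fosb and Atf3 rose by 1.01 ± 0.154 and 0.88 ± 0.128 (edgeR adjusted p = 0.0263 for both). Of 29 immediate early and heat shock genes 3 rose and 3 fell (6 and 7 adjusted over the list alone; 1 rose with the offset), and the list did not stand apart (camera adjusted p = 0.913). Tcf15 went from 113 to 70.5 CPM (-0.78 ± 0.122, edgeR adjusted p = 0.0265) and Myod1 from 153 to 125 CPM (-0.38 ± 0.074, edgeR adjusted p = 0.031), whereas Mef2c, a later regulator of muscle differentiation, went from 255 to 370 CPM (0.44 ± 0.092, edgeR adjusted p = 0.0382). Mef2c and Myod1 were the members of the 35 myogenic genes tested that rose and fell, 1 in each direction, also adjusted over the list alone. Of 49 matrix genes 1 rose and 2 fell (7 and 3 adjusted over the list alone), Col5a2 at 0.86 ± 0.172 and Pcolce at -0.62 ± 0.12. As a list the matrix was higher (camera adjusted p = 0.015, and adjusted p = 0.84 with an estimated correlation). So was hedgehog signalling (0.049, and adjusted p = 0.84 with an estimated correlation; 1 of 12 rose, 3 adjusted over the list alone), with Ptch1 at 0.48. Oxidative phosphorylation was lower (camera adjusted p = 1.3e-04; 1 of 48 rose and 14 fell, 2 and 28 adjusted over the list alone), as were the cell cycle (0.015; 1 of 44 rose and 7 fell, 1 and 13 adjusted over the list alone) and fatty acid oxidation (0.049; 3 of 25 fell, also adjusted over the list alone). With an estimated correlation the adjusted p was 0.84 for each of these lists too. The glycolytic genes Gapdh and Hk2 went apart, at -0.44 ± 0.061 and 0.74 ± 0.095, within a list of 28 in which 1 rose and 7 fell (2 and 8 adjusted over the list alone). As in the mesenchymal-like class, Gm42418 (-1.08), Camk1d (-0.97) and Lars2 (-0.80) were lower and mt-Nd3 (0.95) was higher. Set against the diet difference of all other cells of the same libraries, no gene of this class passed in edgeR (831 at an unadjusted p under 0.05). In that comparison Mef2c was at 0.0157, Egr1 at 0.18, Myod1 at -1.33 and Mt1 at 1.69. Within the class 1152 of 13740 genes passed, 460 higher and 692 lower (3803 at an unadjusted p under 0.05). With the replicate number as a block 76 passed, and with the numbers crossed between the diets as a block 3146 did. Without control replicate 1 or control replicate 2 no gene passed in edgeR (2148 and 2990 at an unadjusted p under 0.05), without high-fat replicate 2 the count was 2336, and with the length offset it was 15, of which 14 were higher. Of the lists, hedgehog signalling ended without control replicate 1 and without either high-fat library, fatty acid oxidation without either high-fat library, and the matrix and the cell cycle without high-fat replicate 2; 4, 8 and 3 lists were called without control replicate 1, high-fat replicate 1 and high-fat replicate 2. Neither of the 2 lists that passed with the length trends removed was among the 5 lists called here.

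Summed over all cells, which includes changes of cell makeup, Hoxd13, Hoxa13, Tbx15 and Pf4 were higher in the high-fat libraries of E11.5, and Hes5, Nefl, Myl7 and Lyz2 were lower. Hoxd13 and Hoxa13 rose by 0.95 ± 0.059 and 1.06 ± 0.12 (edgeR adjusted p = 0.0101 and 0.0125), and the limb and trunk skeletal regulator Tbx15 went from 28.4 to 47.6 CPM (0.67 ± 0.050, edgeR adjusted p = 0.0125). Of 53 matrix genes 17 rose and 6 fell (21 and 6 adjusted over the list alone), with the laminin gene Lama2 at 0.58, the microfibril gene Fbn2 at 0.44 and Col6a3 at 0.45. Hes5, a Notch target of neural progenitors, went from 69.4 to 35.5 CPM (-1.04 ± 0.130, edgeR adjusted p = 0.0125). The neurofilament gene Nefl (-0.97) and the growth cone gene Stmn2 (-0.85) were also lower, and 6 of 11 neuronal markers fell (7 adjusted over the list alone). Myl7, an atrial myosin light chain, was at -1.13 ± 0.152, the endothelial junction gene Cldn5 at -0.85, and the myeloid gene Lyz2 at -1.06. The platelet factor gene Pf4 went the other way, from 28.0 to 59.9 CPM (1.03 ± 0.205, edgeR adjusted p = 0.0194). Of 48 genes of oxidative phosphorylation 1 rose and 20 fell (3 and 29 adjusted over the list alone; 7 and 3 with the offset), and of 29 genes of cholesterol and fatty acid synthesis 3 rose and 10 fell (3 and 12 adjusted over the list alone; 4 and 6 with the offset). Of 15 anterior Hox genes 7 fell (8 adjusted over the list alone), of which Hoxb1 was at -0.93 and Hoxb2 at -0.62. In all 4858 of 21114 genes passed, 2196 higher and 2662 lower (8030 at an unadjusted p under 0.05). Without control replicate 1 or control replicate 2 no gene passed in edgeR (4695 and 5859 at an unadjusted p under 0.05), and without high-fat replicate 2 the count was 7951. With the length offset it was 1978, of which 1586 were among the 4858, with 56.6% higher against 45.2%. Col6a3, Stmn2 and Cldn5 were not among them (edgeR adjusted p = 0.056, 0.057 and 0.056).

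Diet differences were also called in the other classes of E11.5, 9774 in sum, 4553 higher and 5221 lower. Neural progenitor-like cells gave 3084 genes, but 3 without control replicate 1 and 518 without control replicate 2. Erythroid-like cells gave 2277 (701 without control replicate 1), and mesothelium-like cells 1937 (232 and 364 without control replicates 1 and 2, 797 without high-fat replicate 1). Chondrogenic-like cells gave 892 (451 without control replicate 1, 550 without high-fat replicate 1), and neuronal-like cells 862 (255 without control replicate 1, 454 and 571 without high-fat replicates 1 and 2). Neural crest-like cells gave 629 (383 without high-fat replicate 1). Non-erythroid blood cells gave 53 (195 without control replicate 2, 321 and 583 without high-fat replicates 1 and 2) and epithelial-like cells 40 (226 without control replicate 2, 74 and 244 without high-fat replicates 1 and 2). DESeq2 called 206 and 421 genes in the last 2 classes. The sum was 2171 without control replicate 1, 6152 without control replicate 2 and 2899 with the length offset. Lars2 and Camk1d were lower in the chondrogenic-like class too, at -1.08 ± 0.076 and -1.22 ± 0.105.

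At E13.5 there was 1 distinct library per diet, so no test of diet was made, and the values compare 2 libraries. In the mesenchymal-like class Ly6a, Clec3b, Tnxb and Col5a3 had higher CPM in the high-fat library, and Ibsp and Ifitm5 had lower. Ly6a and Pi16, markers of fibroblast and mesenchymal progenitors, had log2 CPM ratios of 3.72 (95% counting interval 3.06 to 4.46; 20 and 248 UMIs) and 1.75 (1.36 to 2.16). Clec3b, a plasminogen-binding lectin of connective tissue, was at 3.29 (3.01 to 3.59), tenascin X (Tnxb) at 1.95 (1.67 to 2.24) and Col5a3 at 1.95 (1.69 to 2.21). The microfibril gene Mfap5 was at 1.19 (1.09 to 1.29), Ecm1 at 0.61 (0.42 to 0.80) and Col1a1, the main collagen of connective tissue, at 0.54 (0.52 to 0.55; 686 and 996 CPM). In the other direction were Ibsp, bone sialoprotein, at -6.11 (-6.87 to -5.44; 1322 and 18 UMIs), Ifitm5, a gene of osteoblasts, at -1.50 (-1.76 to -1.25) and the sphingomyelinase gene Smpd3 at -1.19 (-1.47 to -0.92). Of 53 matrix genes 41 had a ratio above 0, with a median of 0.123 (counting interval 0.0921 to 0.135), above all 10000 random lists matched on expression. The 23 chondrogenic and osteogenic genes all lay below 0, with a median of -0.323 (-0.375 to -0.286), below all random lists. At Leiden resolution 2 more cells of both libraries were chondrogenic-like and fewer were mesenchymal-like. List medians were not recomputed at that resolution, so fewer skeletal cells within the class were not separated from changes within cells. The medians were 0.0636 for 20 fibro-adipogenic markers (percentile 99.3) and -0.0261 for 25 genes of TGF-beta signalling (17.5). They were -0.177 for 14 myofibroblast genes (percentile 0), 0.146 for 27 myogenic genes (100) and 0.0671 for 44 cell cycle genes (100). Random lists of single genes do not keep together genes that move together, so an extreme percentile does not by itself single out a list. In TGF-beta signalling Ltbp2 was at 0.72 (0.42 to 1.03), Ltbp4 at 0.30, Tgfb1 at 0.28 (0.08 to 0.47) and Tgfbr3 at 0.26. Markers of other cells moved in this class as well, with Cd74 of antigen-presenting cells at 2.25 (1.80 to 2.73), the mast cell protease Cma1 at 1.96 (1.58 to 2.36) and the muscle actin Acta1 at 0.90 (0.77 to 1.03).

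**Figure D4:**
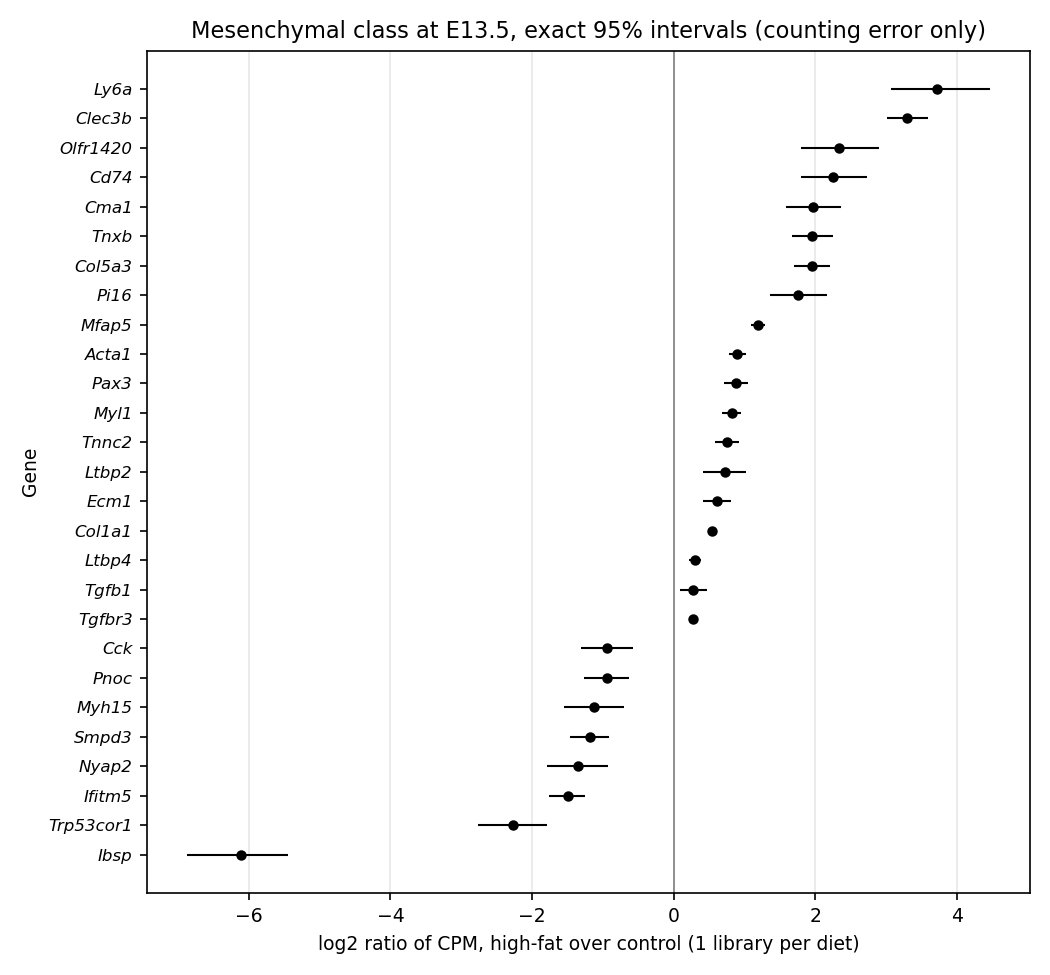
log2 ratio of CPM, high-fat over control, of named genes in the mesenchymal-like class at E13.5 (x axis; 1 library per diet; bars are exact 95% intervals that cover counting error only). Ly6a lies at 3.72 and Ibsp at -6.11.

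In the myogenic-like class of E13.5 the connective tissue genes Dcn (2.31; 2.04 to 2.60), Lum (1.92; 1.54 to 2.33) and Col1a1 (1.46; 1.29 to 1.64) had higher CPM in the high-fat library, as had the creatine kinase gene Ckm (2.25; 2.02 to 2.48) and the late muscle regulator Myf6 (1.61; 1.18 to 2.05). Ckm is a leading gene of cluster 41, which held 24 control and 46 high-fat cells of this class. The fetal myosin gene Myh8 was at -0.56 (-0.67 to -0.45). The 35 myogenic genes had a median of -0.0210 (percentile 48.7), the 45 matrix genes of 0.108 and the 9 fibro-adipogenic markers of 1.0, the last 2 above all random lists. Hbb-y of erythroid cells was at 2.84 (2.77 to 2.91). Over all cells the lymphatic chemokine Ccl21a was at 5.21 (4.89 to 5.54) and the oesophageal keratin Krt4 at 3.23 (3.05 to 3.41), whereas Ibsp (-5.14; -5.66 to -4.66) and the germ cell genes Dppa5a (-4.38; -4.87 to -3.92) and Dppa3 (-3.16; -3.73 to -2.64) had higher CPM in the control library. Chondrogenic-like cells, at this stage mostly cluster 22, led by the cartilage genes Matn1, Acan and Col9a3, made up 4.90% of control cells (exact 95% interval 4.46 to 5.37) and 3.55% of high-fat cells (3.13 to 4.01). At Leiden resolution 2 the class took in more cells, 17.6% (16.8 to 18.4) and 15.1% (14.3 to 16.0). Mesenchymal-like cells made up 62.8% (61.8 to 63.8) and 61.2% (60.0 to 62.3), with overlapping intervals. They made up 66.8 and 67.4% with the stricter cell filter and 47.7% in both libraries at Leiden resolution 2. Of 7093 high-fat cells none was hepatocyte-like, which allows a share of up to 0.0520%.

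Between E11.5 and E13.5 the mesenchymal-like class gained matrix and fibroblast genes and lost proliferation, cholesterol synthesis and anterior Hox genes. Periostin (Postn, ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), a matrix protein of connective tissue, went from 9.10 CPM in control and 10.8 in high-fat libraries at E11.5 to 127 and 160 CPM at E13.5, a log2 difference of 3.64 ± 0.082 (edgeR adjusted p = 1.06e-07). The collagen crosslinking enzyme Lox rose by 3.24 ± 0.080 and Col6a1 by 3.20 ± 0.080 (edgeR adjusted p = 1.06e-07 for both). Of 53 matrix genes 43 rose and 2 fell (44 and 2 adjusted over the list alone). Among 20 fibro-adipogenic markers 15 rose and 2 fell, also adjusted over the list alone, with Dpt at 4.63 ± 0.396 and Thy1 at 3.89 ± 0.214, and of 18 adipogenic genes 9 rose and 2 fell, likewise, with the adipocyte regulators Pparg and Cebpa at 1.72 and 1.60. In TGF-beta signalling 12 of 25 rose and 12 fell, also adjusted over the list alone: the latent binding protein Ltbp3 rose by 2.31, the co-receptor Tgfbr3 by 1.73, and the repressor Skil fell by 1.56. All 44 cell cycle genes fell, also adjusted over the list alone, Bub1 by 1.43 and Rrm2 by 1.37. All 10 genes of the Lin28 axis fell, also adjusted over the list alone, with Lin28a at -3.09 ± 0.259, as did 26 of 29 genes of cholesterol and fatty acid synthesis, with 1 higher (26 and 2 adjusted over the list alone), among them Idi1 at -1.61. Of 48 genes of oxidative phosphorylation 43 fell (44 adjusted over the list alone), with Cox5a at -0.94. For stage no length offset was fitted, whereas between the diets the offset changed the counts of this list. All 15 anterior Hox genes fell, Hoxa4 by 2.95, and of 16 posterior Hox genes 11 rose and 4 fell, with Hoxb13 at 4.82 and Hoxc13 at 2.75, both counts the same adjusted over the list alone. The early patterning genes Barx1, Foxd1 and Tcf15 were at -3.29, -2.65 and -2.10. Markers of other cells moved with stage in this class: 25 of 32 myogenic genes, 7 of 11 neuronal and 6 of 10 macrophage markers rose, also adjusted over the list alone, and Hbb-bs of erythroid cells was at 6.32 ± 0.351. In all 11324 of 18752 genes passed, 5857 higher and 5467 lower, in a fit of 4 libraries of E11.5 against 2 of E13.5 with diet as a term. Stage and collection day cannot be told apart, and clusters 1, 3 and 8 held most of the class at E11.5 and clusters 0, 6, 7, 12, 14 and 19 at E13.5.

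**Figure D5:**
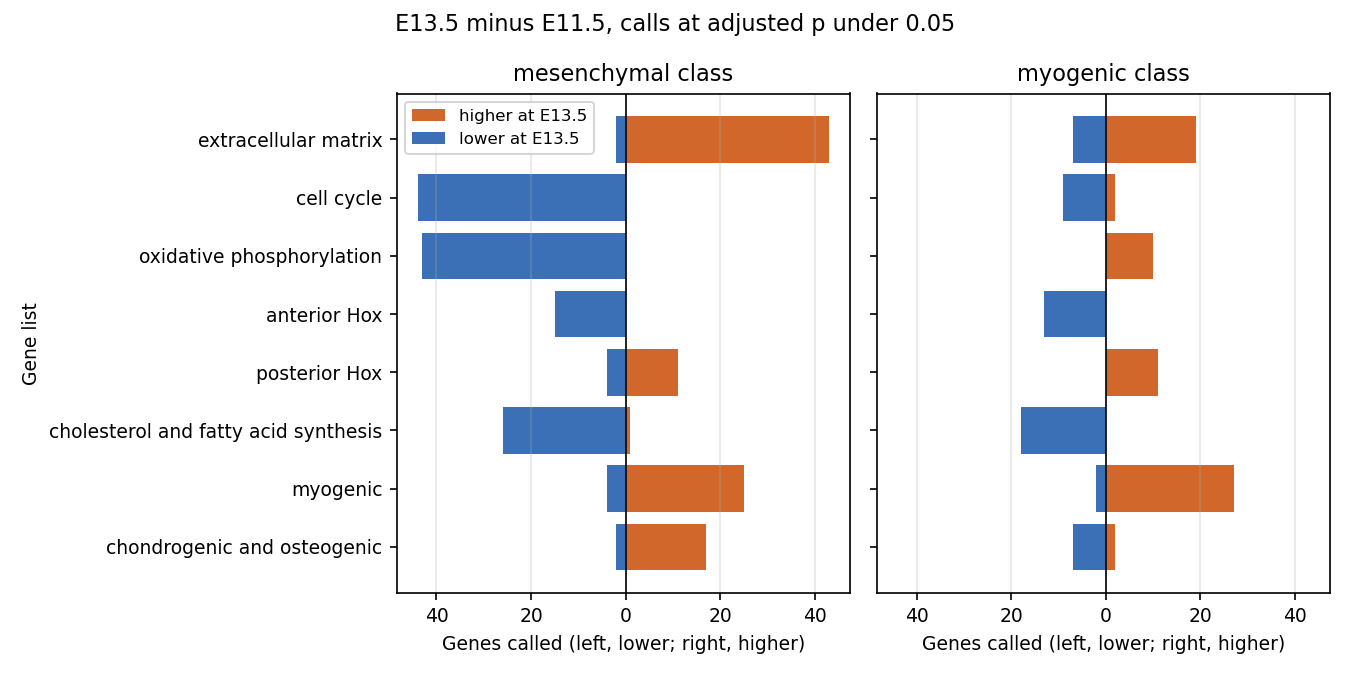
Number of tested genes per list that were lower (left) or higher (right) at E13.5 than at E11.5 in the mesenchymal-like and the myogenic-like class, at an adjusted p under 0.05. In the mesenchymal-like class 43 matrix genes were higher and 44 cell cycle genes lower.

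The myogenic-like class gained genes of the contractile apparatus over the same interval. Troponin Tnni2 (ENSMUSG00000031097, chromosome 7, 142441808 to 142444410) went from 22.1 CPM in control and 31.4 in high-fat libraries to 160 and 242 CPM (2.97 ± 0.086, edgeR adjusted p = 5.4e-08). Tnnt3 rose by 2.38 ± 0.165, the muscle creatine kinase Ckm by 3.49 ± 0.381 and the fetal myosin Myh8 by 1.77 ± 0.142 (edgeR adjusted p = 6.8e-06, 8.8e-05 and 1.56e-05). Of 35 myogenic genes 27 rose and 2 fell (27 and 3 adjusted over the list alone). Pax3, the regulator of migrating muscle precursors, went from 98.0 and 81.1 to 12.8 and 15.4 CPM (-2.58 ± 0.184, edgeR adjusted p = 7.46e-06), and Twist1, an inhibitor of muscle differentiation, fell by 2.32. Of 52 matrix genes 19 rose and 7 fell (19 and 8 adjusted over the list alone), with Col6a1 at 2.13 ± 0.213. Of 48 genes of oxidative phosphorylation 10 rose (9 adjusted over the list alone), among them Ndufa6 at 0.53, and of 28 genes of cholesterol and fatty acid synthesis 18 fell (19 adjusted over the list alone). The Wnt inhibitor Sfrp1 was at -2.85 and Igf1 at -1.65. Of 14 anterior Hox genes 13 fell (14 adjusted over the list alone), Hoxa4 by 3.08. Cluster 27, led by Mylpf and Tnnc1, held 51 and 46 control and 58 and 64 high-fat cells at E11.5, and 132 and 129 at E13.5. Cluster 9, led by Tnnt1 and Itm2a, held 201 and 220 control and 201 and 263 high-fat cells at E11.5, and 321 and 274 at E13.5. Cluster 41, whose leading genes include Tnni2, Tnnt3 and Ckm, had a median of 3272 UMIs per cell. It held 0 and 4 control and 5 and 7 high-fat cells at E11.5, and 24 and 46 at E13.5. Changes of makeup within the class were not separated from changes within cells. In all 4280 of 14585 genes passed, 2214 higher and 2066 lower. Without the control library of E13.5 the count was 2351 and without the high-fat library of E13.5 it was 2603.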

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

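The tests of explanations in this part (anterior Hox genes by class, and Hoxd13 and Hoxa13 with and without limb clusters) were chosen after their results had been seen, and the length offset after the data were seen. Results stand here because a diet difference at E11.5 and the difference at E13.5 went in opposite directions in both libraries of a diet at E11.5 and in the 1 library per diet at E13.5. None of these differences between stages was tested, and results with the same direction at both stages are not listed: across genes, which are not independent replicates, the diet fold changes of E11.5 and E13.5 had a rank correlation of 0.379 in the mesenchymal-like and 0.266 in the myogenic-like class. The share of chondrogenic-like cells was higher in the high-fat libraries at E11.5 (log2 0.69) and lower at E13.5 (-0.463), with different clusters holding the class at each stage; at Leiden resolution 2 its shares at E13.5 were 17.6 and 15.1% in place of 4.90 and 3.55%. Neural progenitor-like cells were lower at E11.5 (-0.79) and higher at E13.5 (0.584), endothelium-like cells lower (-0.68) and higher (0.125), and epithelial-like cells lower (-0.43) and higher (0.167). Mesenchymal-like cells (0.12 at E11.5, not called; -0.0382 at E13.5) and neural crest-like cells (0.42 at E11.5, not called; -0.0977 at E13.5) went the other way. For endothelium-like, epithelial-like, mesenchymal-like and neural crest-like cells the exact 95% intervals of both libraries of E13.5 overlapped. The mesenchymal-like share at E13.5 was not lower in the high-fat library with the stricter cell filter (66.8 and 67.4%). The anterior Hox list had a median of -0.27 in the mesenchymal-like class at E11.5 (-0.10 with the length offset) and of 0.138 at E13.5.

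At E11.5 in the mesenchymal-like class 6 of 15 posterior Hox genes rose (camera adjusted p = 0.0503 for the list) and 5 of 15 anterior ones fell, and the share of neural progenitor-like cells was lower. A more posterior part of the body collected from high-fat embryos may lower anterior Hox genes in every tissue. The anterior list had a median of -0.274 in the mesenchymal-like class (-0.10 with the length offset) and -0.226 in myogenic-like cells (SE 0.102, -0.0614 with the offset). In neural progenitor-like cells it was 0.0123 (SE 0.0724, 0.15 with the offset), and in neuronal-like cells 0.00327 (SE 0.0904, 0.0538 with the offset). Posterior Hox genes were higher in neural progenitor-like (median 0.254, SE 0.0926) and myogenic-like cells (0.315, SE 0.12). These SEs come from resampling list members, which are not independent replicates, and do not measure the spread between libraries. As the classes differ, the explanation of a more posterior part stays open. More distal limb cells could raise Hoxd13, and limb clusters held a larger share of the class in both high-fat libraries. Without these clusters the Hoxd13 difference was 0.474, against 0.844 in the class, and within them it was 0.591 (edgeR adjusted p = 0.00359). Hoxa13 was at 0.781 without them, against 0.885 in the class, and at 0.583 within them. The larger share of limb clusters could account for part of these differences at most, while distal cells within the clusters were not counted. An effect of the diet on patterning is also open and cannot be told apart from these explanations.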

How the results depend on the processing

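The offset for gene length, the removal of length trends from the list tests, the crossed numbers, the class set against all other cells, the added clusters, and the DESeq2, leave-one-out and control-only fits of stage in the myogenic-like class were chosen after the data were seen; the other settings were planned. Leaving out a library leaves 1 in its group, which is then assumed to vary like the others, and the cause of the changes given here was not tested unless stated. Genes called between diets in the mesenchymal-like class, 4828, were 957 to 5758 when each library was left out (942 of the 957 and 2825 of the 2934 without control replicate 2 were among the 4828), 2826 with thinned cells (2633 shared), 2637 with the offset, and none against all other cells (edgeR; 1736 at an unadjusted p under 0.05; DESeq2 called 3734 in the class). In the other settings they were 3734 to 5805. In the myogenic-like class 1152 became 0 to 2336 when each library was left out (edgeR; 2148 at an unadjusted p under 0.05 without control replicate 1, 2990 without control replicate 2; DESeq2 called 1238 with all libraries), 2196 without the filter on low counts, 15 with the offset (all shared) and none against all other cells (edgeR, 831 at an unadjusted p under 0.05). Over all cells 4858 became 0 to 7951 when each library was left out (edgeR; 4695 and 5859 at an unadjusted p under 0.05 without control replicates 1 and 2; DESeq2 called 5075) and 1978 with the offset. Other classes in sum, 9774, gave 2171 to 11880 when each library was left out and 2899 with the offset.

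Per the labels 1 control and 1 high-fat sample were collected per day on 2 days, so libraries may pair by day. Whether same or crossed numbers mark a day is not given. Deviations of same-numbered libraries correlated at -0.170 in the mesenchymal-like, -0.00549 in the myogenic-like and -0.292 in the neural progenitor-like class, and -0.113 over all cells. With 2 libraries per diet, crossed numbers give the same value with the opposite sign. These values therefore leave pairing by crossed numbers open, and the main tests hold no term for the day. With the replicate block 4763 genes (4416 shared) were called in the mesenchymal-like class and 3939 (3722 shared) over all cells. In the myogenic-like class 76 were (73 shared), of which 68.4% were higher, against 39.9% without the block. The other classes gave 11782 in sum. Of shares, 5 of 13 were called, and of lists 7 in the mesenchymal-like and 7 in the myogenic-like class. With crossed numbers as a block the mesenchymal-like class, the myogenic-like class and all cells gave 5587, 3146 and 5601 genes. No paired analysis was possible for stage and at E13.5 because numbers do not cross stages and E13.5 has 1 distinct library per diet.

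Against 6 shares called, 0 to 6 were called when each library was left out, 0 to 4 of them among the 6 (edgeR; without control replicate 1, 3 at an unadjusted p under 0.05; no other tool was run), 3 with the stricter cell filter and 3 with erythroid cells left out of the total. With the stricter filter epithelial-like (-0.43, adjusted p = 0.092), erythroid-like (0.45, 0.25) and neuronal-like cells (-0.44, 0.18) missed the threshold. Without erythroid cells epithelial-like (-0.38, 0.075) and neuronal-like cells (-0.41, 0.075) did. Shares that were not called changed sign: blood ranged from -0.0519 without control replicate 2 to 0.114 without control replicate 1 and was at -0.049 with doublets kept, mesothelium from -0.228 without control replicate 1 to 0.173 without control replicate 2 and was at 0.00644 with erythroid cells left out, and cardiomyocytes were at 0.108 at Leiden resolution 2. Against 6 lists in the mesenchymal-like class, 6 to 8 were called when each library was left out, 4 to 6 of them among the 6, and none with fry (10 at an unadjusted p under 0.05) or an estimated correlation in camera (0 at an unadjusted p under 0.05), and 2 with length trends removed (1 shared). Against 5 lists in the myogenic-like class, 3 to 9 were called when each library was left out, 1 to 5 of them among the 5, and none with an estimated correlation in camera (0 at an unadjusted p under 0.05) and 2 with length trends removed (0 shared). Stage counts were 9633 to 11587 in the mesenchymal-like class over all settings (11324) and 2351 to 4142 in the myogenic-like class (4280) when each library was left out. Named genes kept their direction in the settings run, except against all other cells, where 18 of 72 in the mesenchymal-like and 7 of 43 in the myogenic-like class had the opposite sign. In the mesenchymal-like class 1091 of 1146 gene values kept their side of the threshold and 55 lost it, in the myogenic-like class 418 of 593, over all cells 377 of 455, for stage 400 of 400 and 296 of 300. At E13.5 3 of 87 ratios moved beyond their counting interval. At 1.5-fold the simulated tests found 64 of 100 genes in the myogenic-like class, which has fewer UMIs.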

Other observations

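Of the tests of explanations in this part, those of a shared length trend and of libraries entering both contrasts were planned before their results were seen, and those of depth, cell makeup, preparation, maternal diet and older embryos were chosen after, as was the length offset. In neural progenitor-like cells the neurofilament genes Nefl and Nefm were lower in the high-fat libraries (-2.0 ± 0.333 and -1.72 ± 0.273, edgeR adjusted p = 0.00532 and 0.00463), as were the growth cone genes Gap43 (-1.15) and Stmn2 (-1.13) and the proneural regulator Neurog1 (-1.10). Nefl, Nefm, Gap43 and Stmn2 are neuron genes, the share of neuronal-like cells was lower too (log2 -0.45), and whether these differences belong to the progenitor cells was not tested. In neuronal-like cells the homeobox genes Hmx1 and Phox2a of sensory and autonomic neurons were at -1.27 ± 0.159 and -1.26 ± 0.167. The Notch pathway genes Hes1 and Notch1 and the neurogenic gene Neurod4 were higher there, at 1.24, 1.19 and 1.20. The count of called genes in neural progenitor-like cells went from 3084 to 3 without control replicate 1 and to 518 without control replicate 2, and in neuronal-like cells from 862 to 255 without control replicate 1 and to 454 and 571 without high-fat replicates 1 and 2.

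Single genes differed in other classes too. In erythroid-like cells the carbonic anhydrase gene Car1 (-1.07 ± 0.102) and Apoe (-1.18 ± 0.083) were lower and the nuclear RNA Malat1 was higher (0.81 ± 0.10). In mesothelium-like cells the keratins Krt8 (-0.97 ± 0.073) and Krt18 (-0.85 ± 0.071) were lower and the growth factor gene Nrg1 (1.0 ± 0.081) was higher. In epithelial-like cells Fgf8, a signal of limb and tail bud ectoderm, went from 238 to 98.7 CPM (-1.30 ± 0.196, edgeR adjusted p = 0.0439; -1.09 and 0.132 with the length offset). In neural crest-like cells the limb mesenchyme gene Prrx1 was at 2.05 ± 0.333 and the glial regulator Sox8 at -0.93 ± 0.205 (-0.79, edgeR adjusted p = 0.123 with the offset). In non-erythroid blood cells the lysozyme gene Lyz2 went from 1112 to 545 CPM (-1.09 ± 0.129, edgeR adjusted p = 0.0324). These classes gave 2277, 1937, 40, 629 and 53 called genes in this order. The counts were 701 in erythroid-like cells without control replicate 1, 232, 364 and 797 in mesothelium-like cells without control replicates 1 and 2 and high-fat replicate 1, and 383 in neural crest-like cells without high-fat replicate 1. In epithelial-like cells they were 226, 74 and 244, and in blood cells 195, 321 and 583, without control replicate 2, high-fat replicate 1 and high-fat replicate 2.

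Fold changes between diets at E11.5 rose with gene length in every class with at least 50 cells in each library, erythroid-like cells included. Depth as the whole cause was excluded, since without high-fat replicate 1, the deepest library, the rank correlation in the mesenchymal-like class was 0.566. A changed mix of clusters within classes was excluded as the whole cause too, since the median over single clusters was 0.477. Mesothelium-like and neural crest-like cells are 1 cluster each, at 0.5471 and 0.4998 both as class and as cluster. A change of makeup inside clusters was not tested. A difference in library preparation between the diet groups may account for the trend, as the lowest class stood at 0.405. Replicates of 1 diet (control, then high-fat) differed by 0.327 and -0.363 in the mesenchymal-like class. In neural progenitor-like cells they differed by only -0.00661 and -0.12, and in non-erythroid blood by -0.015 and 0.035. An effect of the maternal diet on RNA in every class may account for the trend as well, but at E13.5 the mesenchymal-like correlation was 0.206, no larger than between replicates. In the other classes at E13.5 it lay between -0.0256 (neural crest-like) and 0.234 (neuronal-like). In non-erythroid blood it was 0.0851, above the value between its replicates. As diet and preparation cannot be told apart with 2 libraries each, lower oxidative phosphorylation in the mesenchymal-like class, where 2 of 48 genes rose and 29 fell without the length offset and 8 rose and 6 fell with it, stays open too.

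Diet differences at E11.5 lay along the stage difference in the mesenchymal-like class, with a rank correlation of 0.323 across genes, which are not independent replicates. The same libraries entering both contrasts were excluded as the whole cause: with separate pairs of libraries the correlation was 0.314 (0.301 to 0.326 over the splits). The covariance was 0.0428 with separate pairs and 0.0423 with shared libraries. Simulated libraries without an effect gave 0.00276 (covariance -6.65e-05). All of them were given equal noise, for which a value near 0 is fixed in advance, so the simulation decides nothing here. A length trend shared by both contrasts may be part of it, since the value fell to 0.158 with exon and intron length regressed out, between the bounds set for either outcome. Older embryos in the high-fat pools could give it too, but the correlation was 0.0351 in myogenic-like cells at E11.5, -0.149 in mesenchymal-like cells at E13.5 and -0.0907 in myogenic-like cells at E13.5, where the libraries of E13.5 enter both contrasts and no value without an effect was simulated. These values decide nothing, also as the spread set against them, 0.103, is of the E11.5 libraries and was added after values were seen (without it the bound of 0 would have excluded older embryos), so that age and an effect of the diet stay open.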
